A study of Mus musculus with 21 samples.

How the data were processed

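RNA was measured in 21 libraries of B cells sorted from mouse spleen, mesenteric lymph nodes (mLN) and Peyer's patches (PP), with single-end reads on an Illumina HiSeq instrument, per the labels. The labels name both a TruSeq and a Nextera XT kit, so the kit is uncertain, and strand was not used to tell a gene from its antisense partner. The values analysed were whole-number counts per gene as deposited by the authors. Per the submitters' processing notes, STAR, HTSeq, DESeq2 and the mouse build mm10 were used, and their roles, versions and settings are not given in the sources used here. The table holds 23337 gene symbols, of which 20929 were found in the GENCODE M21 annotation of that build, from which the coordinates were taken. Older symbols are printed as the table gives them. Each column was matched to its library by its name.

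Genes were filtered with filterByExpr by group, libraries were scaled with TMM, and groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05. The 9 comparisons of HEL pos and BCL2 HEL pos cells and both interactions came from 1 fit of 18 libraries in 6 groups (11419 genes, 12 residual degrees of freedom, biological coefficient of variation 0.207). HEL pos and HEL neg cells were compared in a fit of 12 libraries with tissue as a covariate (11406 genes, 8 residual degrees of freedom, 0.259), because HEL neg cells have 1 pool per tissue. Levels of single genes are in CPM of TMM-scaled library totals, while the summed enterocyte, Y-linked and receptor transcripts, Xist and Rn45s are shares of the plain library total. A floor of 3 counts came to 0.265 to 0.548 CPM per library, which covers counting error only. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over 31 lists within a comparison. Over all comparisons 23 of 143 camera calls held with the estimated correlation.

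The groups, tests, gene lists, the rule for named genes and all alternatives not described as added later were chosen before the data were examined. Named genes were the 8 highest and 8 lowest fold changes among called genes with an average log2 CPM of at least 3 and groups that did not overlap, plus at most 4 called members of each list and Bcl2 in every comparison. For each interaction they were the 8 genes with the smallest p, and some of the selection is not reported here, mostly for length. By chance 10% of genes have groups of 3 that do not overlap. The alternatives were DESeq2 1.42.0, its size factors within edgeR, no low-count filter, each library left out in turn, only the libraries compared, and the library number as a block. Added after the data were seen were fits without the pooled HEL pos libraries, against the pooled library alone with the spread of the other groups, and without the PP HEL pos libraries 399 and Pool, whose olfactory and vomeronasal receptor transcripts (714 and 937 CPM) exceed the other libraries.

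The tests were checked on simulated counts with 200 changed genes, drawn from genes with a mean of at least 8 CPM. Recovery of changes in lower genes was not tested. For PP against spleen HEL pos cells (11170 genes) edgeR recovered 20.9%, 74.6% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, with 6 false calls among 136, and DESeq2 31.3%, 80.6% and 100%, with 18 among 159. For the interaction of BCL2 with PP against spleen (11182 genes) edgeR recovered 4.48%, 40.3% and 81.8%, and for HEL pos against HEL neg cells (11149 genes) 16.4%, 71.6% and 98.5%. On counts simulated for PP against spleen HEL pos cells (11419 genes), camera called a raised list of 20 genes and 0 of 200 unchanged lists. The simulated genes were drawn independently, so this check cannot show how camera behaves with correlated genes. In the real data of that comparison the estimated correlation reached 0.88, for cytosolic ribosomal protein genes. The table has 0 immunoglobulin segment or constant genes and 0 mitochondrially encoded genes, so the planned shares of immunoglobulin classes were left out.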

Results

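The series holds bulk RNA sequencing counts of B cells sorted from the spleen, the mesenteric lymph nodes (mLN) and the Peyer's patches (PP, lymphoid follicles in the wall of the small intestine) of C57BL/6 mice. Its stated subject is self-reactive B cells of the gut. The labels name 3 kinds of B cells, HEL neg, HEL pos and BCL2 HEL pos, without expanding HEL or BCL2. Each tissue has 1 pooled library of HEL neg cells, 3 libraries of HEL pos cells (a pool, 392 and 399) and 3 libraries of BCL2 HEL pos cells (922, 926 and 950), 21 libraries in all. Library totals ran from 5475131 to 11340876 counts, and 12747 to 18206 genes had at least 1 count. No pair of libraries was the same within sampling noise, and Spearman correlations across genes between libraries of 1 group lay between 0.946 and 0.989. The labels do not say whether the numbered libraries come from single mice, so every p-value measures the spread between these libraries, which may be technical in part.

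Principal components of the 1000 most variable genes placed the tissues of HEL pos and BCL2 HEL pos cells apart, with 31.4% of the variance on the first component and 19.4% on the second. Transcripts of enterocytes, the absorptive cells of the gut lining, came to 892 CPM (counts scaled to a common library total) in PP HEL neg cells, 561 ± 325 (SD, n = 3) in PP HEL pos cells and 86.5 ± 76.7 (SD, n = 3) in PP BCL2 HEL pos cells. The highest value in any spleen or mLN library was 3.27 CPM. Along the first component the PP libraries lay in the order of these transcripts. They ran from 64.5 in HEL neg cells (892 CPM) to -12.7 in the BCL2 HEL pos library 922 (8.97 CPM). Spleen and mLN libraries overlapped on that component. Y-linked transcripts were at most 0.869 CPM in the HEL pos libraries 392 and 399 of all tissues and 92.3 to 168 CPM in all other libraries, while Xist was present in every library at 79.3 to 608 CPM. All BCL2 HEL pos libraries thus held both, with Y-linked transcripts at 92.3 to 161 CPM and Xist at 142 to 278 CPM. Since Xist marks female cells, these values argue against a single mouse as the source of any BCL2 HEL pos library.

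**Figure D1:**
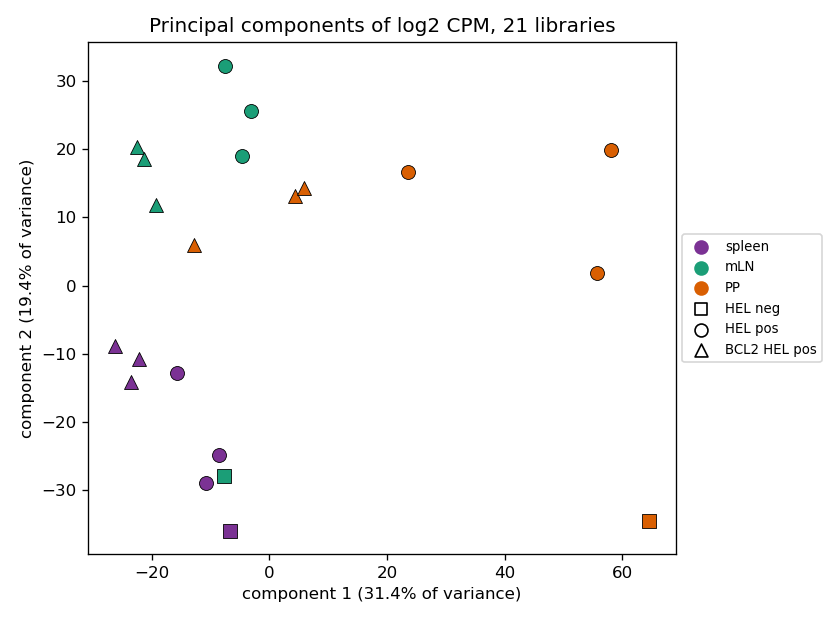
Position of the 21 libraries on the first and second principal components of log2 CPM, with colour for tissue and shape for the kind of B cell. The 3 PP HEL pos libraries and the PP HEL neg library lie at the highest values of component 1, which carries 31.4% of the variance.

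HEL pos cells of PP were set against those of spleen to find how these B cells differ in the gut. Nr4a1, Egr1, Egr2 and Egr3, transcription factors induced by antigen receptor signalling, were higher in PP by 2.75 ± 0.29, 2.54 ± 0.24, 4.40 ± 0.33 and 2.29 ± 0.38 on the log2 scale (SE, 3 libraries each). Egr2 stood at 104 ± 11.3 CPM in PP and 5.03 ± 0.737 CPM in spleen (SD, n = 3), with an adjusted p of 2.85e-08. The activation marker Cd83 rose by 2.23 ± 0.16, to 1611 ± 79.9 CPM from 352 ± 21.7 CPM, and the chemokine gene Ccl4 rose by 5.44 ± 0.59. Genes of marginal zone B cells fell, among them the complement receptor Cr2 at -1.36 ± 0.18, Cd1d1 at -1.69 ± 0.18 and the receptor Notch2 at -1.06 ± 0.15. Nr4a1 lies on chromosome 15 from 101254269 to 101274795 and Egr2 on chromosome 10 from 67535475 to 67542188 (mm10).

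Of 24 tested genes of B cell anergy and tolerance, 11 rose in PP and 2 fell (13 up and 3 down when adjusted over the list alone; camera adjusted p = 9.94e-07, and adjusted p = 0.00219 with an estimated correlation). Besides Egr2, Egr3 and Nr4a1 they included Cd72, an inhibitory receptor of B cells, at 0.83 ± 0.15. Among 13 marginal zone genes 10 fell (11 down when adjusted over the list alone; camera adjusted p = 8.49e-13, and adjusted p = 0.034 with an estimated correlation). The tetraspanin Cd9 stood at -3.17 ± 0.66 and the ubiquitin ligase subunit Asb2 at -3.56 ± 0.62. The marginal zone list was also lower in HEL neg cells of PP than of spleen, at a median of -1.13 between the pools. The HEL pos pools gave -1.50, with 1 library each in a comparison made after the data were seen. The lower marginal zone genes were thus not particular to HEL pos cells. Of 23 components of antigen receptor signalling 11 fell and 2 rose (2 up and 11 down when adjusted over the list alone; camera adjusted p = 1.14e-05, and adjusted p = 0.104 with an estimated correlation). Cd79b, a signalling chain of the B cell receptor, fell from 5056 ± 657 CPM in spleen to 2476 ± 506 CPM in PP, and the kinase Syk changed by -1.05 ± 0.17. The immediate early list split, with 9 of 20 genes up and 4 down (10 up and 7 down when adjusted over the list alone; camera adjusted p = 6.18e-05, and adjusted p = 0.168 with an estimated correlation). Glycolysis genes rose in 7 of 17 cases, among them Pfkp at 1.37 ± 0.22, Ldha at 0.78 ± 0.14 and Tpi1 at 0.60 ± 0.12 (9 up when adjusted over the list alone; camera adjusted p = 0.00136, and adjusted p = 0.168 with an estimated correlation).

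Other groups of genes also differed between PP and spleen HEL pos cells. Interferon-stimulated genes fell in 7 of 26 cases, with Gbp2 at -1.39 ± 0.28 (9 down when adjusted over the list alone; camera adjusted p = 4.01e-05, and adjusted p = 0.305 with an estimated correlation). Among 17 Toll-like receptor genes 3 fell, Tlr3 at -3.88 ± 0.70 (7 down when adjusted over the list alone; camera adjusted p = 0.00578, and adjusted p = 0.042 with an estimated correlation). In the list of TGF-beta response and IgA switching genes 5 of 16 rose and 1 fell (7 up and 1 down when adjusted over the list alone; camera adjusted p = 0.0355, and adjusted p = 0.168 with an estimated correlation). The receptor Tgfbr1 stood at 1.59 ± 0.26, the SMAD repressor Skil at 1.11 ± 0.19 and Tgif1 at 1.29 ± 0.21. Homing genes went both ways: the gut-homing integrin chain Itgb7 was lower, changing by -1.12 ± 0.15, the sphingosine phosphate receptor S1pr4 by -1.16 ± 0.14 and the transcription factor Klf2 by -1.48 ± 0.28. Gpr183, an oxysterol receptor that positions B cells, was higher by 0.93 ± 0.14. The antiapoptotic genes Bcl2a1d and Bcl2a1b, whose near-identical copies make their counts uncertain, were higher by 2.13 ± 0.28 and 1.62 ± 0.24. Bcl2 itself changed by -0.12 ± 0.24 (adjusted p = 0.79). Irf4 and Bhlhe40, transcription factors of activated B cells, rose by 1.21 ± 0.17 and 1.56 ± 0.20, Trib1 by 1.97 ± 0.34, the ligand gene Pdcd1lg2 by 1.81 ± 0.23 and the kinase Lck by 2.65 ± 0.21. The short-chain fatty acid receptor Ffar2 changed by -3.94 ± 0.63.

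Markers of other cell types moved along with these groups. Epithelial markers rose in 11 of 13 cases (13 up when adjusted over the list alone; camera adjusted p = 5.09e-14, and adjusted p = 0.0403 with an estimated correlation). The apolipoprotein genes Apoa1 and Apoa4, the goblet cell gene Zg16 and the fatty acid carrier Fabp1 had no count in spleen HEL pos libraries and were at least 1049-fold, 1100-fold, 647-fold and 346-fold higher in PP, taking 3 counts over the spleen group as the floor. Fabp2 stood at 106 ± 49.4 CPM in PP and 0.469 ± 0.625 CPM in spleen. Granulocyte markers fell in 4 of 6 cases (camera adjusted p = 4.01e-05, and adjusted p = 0.0803 with an estimated correlation), S100a8 from 49.2 ± 47.5 CPM in spleen to 0.193 ± 0.217 CPM in PP, and Ngp, with no count in PP, by at least 52.8-fold. In all, 1756 of 11419 genes were called between PP and spleen HEL pos cells, 907 higher and 849 lower (edgeR quasi-likelihood test, adjusted p under 0.05), of which 717 differed by more than 2-fold. A fit of the 6 compared libraries alone called 800, and without the PP libraries 399 and Pool, chosen after the data were seen for their receptor and enterocyte background, the count was 640.

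HEL pos cells of mLN differed from those of spleen in 2794 of 11419 genes, the highest count among the comparisons made here, with 1476 higher and 1318 lower. Axl, a receptor tyrosine kinase of the TAM family, rose by 7.54 ± 0.37 on the log2 scale, from 1.11 ± 0.333 to 213 ± 19.9 CPM (adjusted p = 4.11e-11). The chemokine genes Ccl4 and Ccl3 were higher by 7.73 ± 0.58 and 5.42 ± 0.79, the lysosomal tetraspanin Cd63 by 7.11 ± 0.49, the G-protein regulator Rgs1 by 5.92 ± 0.54, plakoglobin (Jup) by 5.39 ± 0.53 and neurogranin (Nrgn) by 4.89 ± 0.40. Egr2, Nr4a1 and Egr1 rose by 4.91 ± 0.33, 2.90 ± 0.29 and 2.52 ± 0.24, and Cd83 by 1.98 ± 0.16. Cr2 changed by -2.42 ± 0.19, Cd1d1 by -2.27 ± 0.18 and the sterol hydroxylase Cyp39a1 by -3.73 ± 0.35. Axl lies on chromosome 7 from 25757273 to 25788705 (mm10).

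The anergy and tolerance list had 11 genes up and 3 down of 24 in mLN against spleen (11 up and 3 down when adjusted over the list alone; camera adjusted p = 2.08e-04, and adjusted p = 0.0117 with an estimated correlation). Folr4, a folate receptor family gene listed there, rose by 4.82 ± 0.61 and Cd5, a negative regulator of receptor signalling, by 2.31 ± 0.38, both also known from T cells, whereas the ubiquitin ligase gene Cblb changed by -1.23 ± 0.17. Of 11 follicular B cell genes 7 fell and 1 rose (1 up and 7 down when adjusted over the list alone; camera adjusted p = 4.26e-06, and adjusted p = 0.00628 with an estimated correlation). The follicle-homing receptor Cxcr5 stood at -1.48 ± 0.15, the egress receptor S1pr1 at -1.49 ± 0.14 and Itgb7 at -1.71 ± 0.15. Marginal zone genes fell in 9 of 13 cases, Notch2 at -1.40 ± 0.15 (11 down when adjusted over the list alone; camera adjusted p = 3.28e-10, and adjusted p = 0.0407 with an estimated correlation). Their median between the mLN and spleen pools was -0.81 in HEL neg cells and -1.57 in HEL pos cells, with 1 library each. Receptor signalling components had 11 down and 2 up of 23 (2 up and 12 down when adjusted over the list alone; camera adjusted p = 6.79e-07, and adjusted p = 0.0592 with an estimated correlation). The inhibitory lectin Cd22 stood at -1.12 ± 0.12 and Syk at -1.50 ± 0.17. The germinal centre regulator Bcl6 changed by -1.04 ± 0.16.

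Part of the secretion, oxidative phosphorylation and glycolysis lists was higher in mLN HEL pos cells, but their camera calls were lost with the estimated correlation. The unfolded protein response and secretion list had 15 of 22 genes up (15 up when adjusted over the list alone; camera adjusted p = 2.50e-06, and adjusted p = 0.167 with an estimated correlation). The chaperone Calr stood at 1.06 ± 0.15, the disulfide isomerase Pdia6 at 1.16 ± 0.19 and Sdf2l1 at 1.55 ± 0.23. Derl3, Sdc1 and Slamf7, known from plasma cells, rose by 2.22 ± 0.27, 2.42 ± 0.30 and 1.67 ± 0.18, and Irf4 by 1.45 ± 0.17, while the J chain gene (Igj) changed by -3.85 ± 0.68. Oxidative phosphorylation genes rose in 16 of 26 cases (20 up when adjusted over the list alone; camera adjusted p = 5.66e-06, and adjusted p = 0.229 with an estimated correlation). Atp5b stood at 0.69 ± 0.11 and cytochrome c (Cycs) at 0.75 ± 0.14. Glycolysis genes had 9 up and 1 down of 17 (10 up and 1 down when adjusted over the list alone; camera adjusted p = 1.10e-04, and adjusted p = 0.0939 with an estimated correlation), Pfkp at 2.37 ± 0.22. DNA replication genes rose in 8 of 23 cases (9 up when adjusted over the list alone; camera adjusted p = 0.00582, and adjusted p = 0.251 with an estimated correlation). Mcm5 stood at 0.81 ± 0.13, Mcm6 at 0.84 ± 0.14 and Pcna at 1.02 ± 0.22. In the list of BCL2 family genes 4 of 14 rose and 2 fell (5 up and 2 down when adjusted over the list alone; camera adjusted p = 0.00957, and adjusted p = 0.0592 with an estimated correlation). The proapoptotic Bcl2l11 rose by 2.05 ± 0.21 and the antiapoptotic Bcl2a1d by 2.85 ± 0.28, with Bcl2 at 0.06 ± 0.23 (adjusted p = 0.895).

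T and NK cell markers rose in 5 of 14 cases in mLN (5 up when adjusted over the list alone; camera adjusted p = 9.02e-04, and adjusted p = 0.202 with an estimated correlation). Lck, a T cell kinase that some B cells also express, stood at 343 ± 25.6 CPM in mLN and 34.9 ± 12.2 CPM in spleen HEL pos cells, while Cd3e, part of the T cell receptor complex, stood at 7.27 ± 4.6 and 0.539 ± 0.391 CPM. Erythroid and platelet markers fell in 4 of 5 cases (camera adjusted p = 0.0138, and adjusted p = 0.167 with an estimated correlation). Granulocyte markers fell in 4 of 6 cases (camera adjusted p = 7.59e-05, and adjusted p = 0.0862 with an estimated correlation). The haemoglobin gene Beta-s went from 54.6 ± 27.2 to 0.88 ± 1.52 CPM, and the granulocyte gene S100a8 from 49.2 ± 47.5 to 0.0419 ± 0.0726 CPM. Il9r, the interleukin-9 receptor, changed by -3.95 ± 0.60. The count of 2794 genes lay between 2023 and 2528 when 1 library was left out in turn and was 3053 by DESeq2.

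PP and mLN are both gut-associated sites, and HEL pos cells differed between them in 1012 genes, 610 higher and 402 lower in PP (edgeR, adjusted p under 0.05). S1pr1 and Cxcr5 were higher in PP by 1.08 ± 0.14 and 0.93 ± 0.15 on the log2 scale. In the follicular list 5 of 11 genes rose (7 up when adjusted over the list alone; camera adjusted p = 1.22e-05, and adjusted p = 0.0104 with an estimated correlation). Cr2 was higher by 1.06 ± 0.18, Bcl6 by 0.96 ± 0.16 and the ligand gene Icosl by 1.34 ± 0.16. Axl, Cd63, Ccl4 and Jup were lower in PP, changing by -2.43 ± 0.25, -2.41 ± 0.34, -2.29 ± 0.39 and -1.99 ± 0.42, with Axl at 38.5 ± 6.51 CPM in PP and 213 ± 19.9 CPM in mLN.

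The TGF-beta response and IgA switching list had 4 of 16 genes up in PP against mLN (6 up when adjusted over the list alone; camera adjusted p = 9.28e-04, and adjusted p = 0.0734 with an estimated correlation). Skil stood at 1.04 ± 0.19 and the interleukin-5 receptor chain Il5ra at 2.03 ± 0.29. Among homing genes 6 of 22 rose and 1 fell (10 up and 2 down when adjusted over the list alone; camera adjusted p = 0.0202, and adjusted p = 0.221 with an estimated correlation). The integrin chain Itga4 stood at 0.74 ± 0.12 and Itgb1 at -0.90 ± 0.15. Interferon-stimulated genes fell in 7 of 26 cases (14 down when adjusted over the list alone; camera adjusted p = 3.14e-06, and adjusted p = 0.221 with an estimated correlation), and the interferon-induced membrane gene Ifitm2, named by its fold, changed by -2.80 ± 0.42. DNA replication genes fell in 8 of 23 cases (12 down when adjusted over the list alone; camera adjusted p = 4.45e-08, and adjusted p = 0.0734 with an estimated correlation). The helicase subunit Mcm6 changed by -0.75 ± 0.14 and Uhrf1, which maintains DNA methylation, by -1.08 ± 0.22. Secretion and unfolded protein response genes fell in 7 of 22 cases (12 down when adjusted over the list alone; camera adjusted p = 5.32e-06, and adjusted p = 0.221 with an estimated correlation). Vpreb3 rose by 1.21 ± 0.23, lymphotoxin beta (Ltb) by 0.92 ± 0.16, Tlr1 by 0.68 ± 0.14, Cpne5 by 3.35 ± 0.53, the signalling genes Cblb and Prkcb by 0.80 ± 0.17 and 0.75 ± 0.14, and Atxn1 changed by -1.97 ± 0.34.

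Epithelial markers rose in 12 of 13 cases in PP against mLN (12 up when adjusted over the list alone; camera adjusted p = 1.14e-17, and adjusted p = 0.0317 with an estimated correlation). Apoa1 was at least 1224-fold and the keratin gene Krt8 at least 323-fold higher, both without a count in mLN HEL pos libraries and with a floor of 3 counts over that group. Fabp2 stood at 106 ± 49.4 and 0.575 ± 0.68 CPM. T and NK cell markers had 3 down and 1 up of 14 (1 up and 6 down when adjusted over the list alone; camera adjusted p = 0.0107, and adjusted p = 0.358 with an estimated correlation). Erythroid and platelet markers had a median of 2.97 with no member called over all genes (3 up when adjusted over the list alone; camera adjusted p = 0.0305, and adjusted p = 0.221 with an estimated correlation). The count of 1012 called genes became 374 without the mLN library 392, 421 without the mLN library 399, 604 without the PP library 399, 551 without the pooled HEL pos libraries and 209 without the PP libraries 399 and Pool. A fit of the 6 compared libraries alone called 344.

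**Figure D2:**
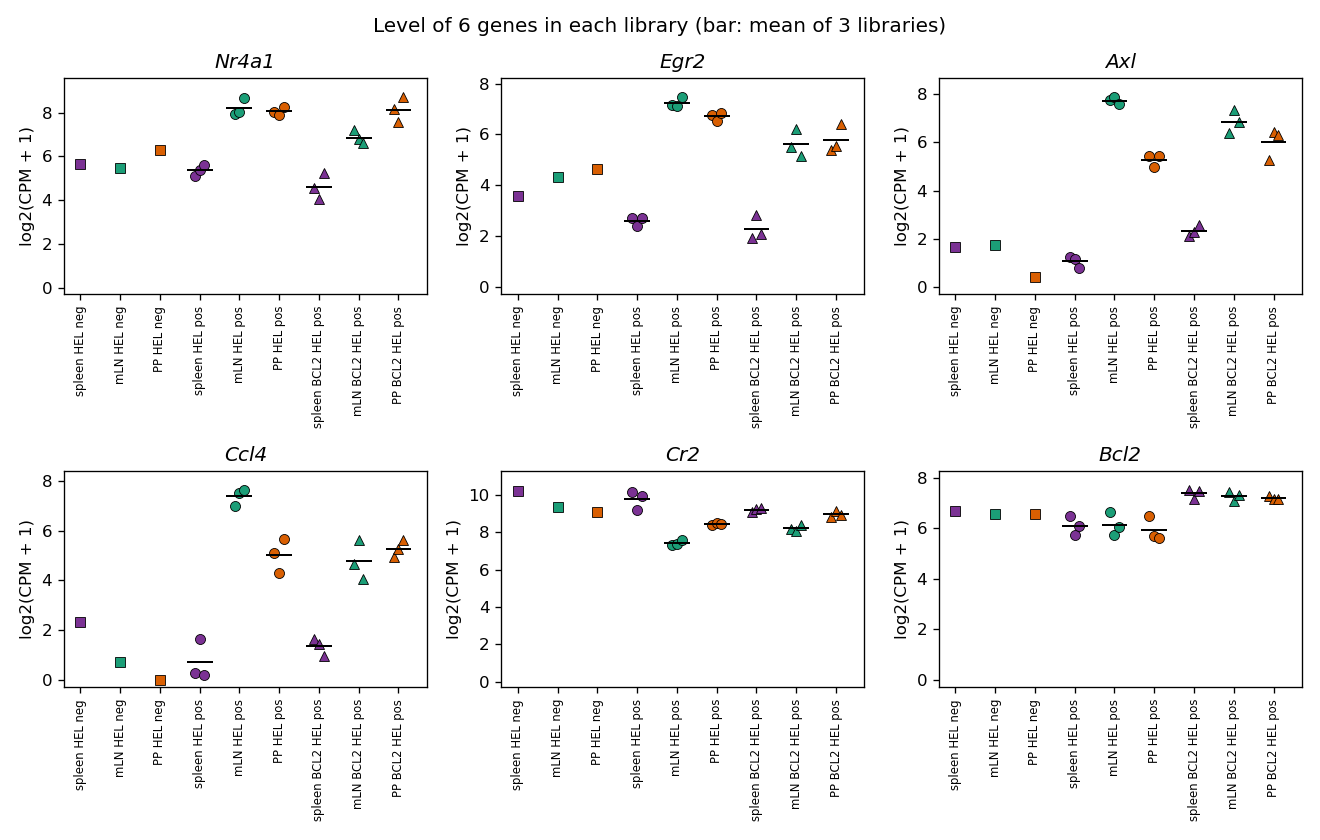
Level of Nr4a1, Egr2, Axl, Ccl4, Cr2 and Bcl2 in each library as log2(CPM + 1), by kind of B cell and tissue, with a bar at the mean of each group of 3 libraries. Axl lies between 193 and 233 CPM in the mLN HEL pos libraries and between 0.737 and 1.37 CPM in the spleen HEL pos libraries.

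The same tissue comparisons were made in BCL2 HEL pos cells. Between PP and spleen, Nr4a1, Egr2 and Egr1 rose by 3.56 ± 0.31, 3.79 ± 0.33 and 2.45 ± 0.25 on the log2 scale, Cd83 by 2.36 ± 0.16, Bhlhe40 by 3.12 ± 0.22 and Ccl4 by 4.56 ± 0.52 (SE, 3 libraries each). Nr4a1 stood at 296 ± 113 CPM in PP and 25 ± 10.8 CPM in spleen (adjusted p = 2.87e-07). The inhibitory receptor Cd300lf rose by 3.50 ± 0.47, the chemokine receptor Ccr1 by 2.23 ± 0.33, Lck by 2.21 ± 0.21, Irf4 by 0.97 ± 0.16 and Derl3 by 1.98 ± 0.28. Klf2 changed by -1.80 ± 0.28, S1pr4 by -1.10 ± 0.14, the scaffold gene Ahnak by -2.54 ± 0.25 and Myadm by -2.38 ± 0.25.

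Anergy and tolerance genes rose in 7 of 24 cases and 1 fell in BCL2 HEL pos cells of PP against spleen (8 up and 1 down when adjusted over the list alone; camera adjusted p = 2.23e-05, and adjusted p = 0.00814 with an estimated correlation). Cd72 stood at 1.38 ± 0.15 and the phosphatase Inpp5d at 0.66 ± 0.12. Glycolysis genes rose in 8 of 17 cases (12 up when adjusted over the list alone; camera adjusted p = 4.20e-09, and adjusted p = 0.0314 with an estimated correlation). Ldha changed by 1.06 ± 0.14 and Tpi1 by 0.82 ± 0.12. Follicular genes fell in 4 of 11 cases (2 up and 5 down when adjusted over the list alone; camera adjusted p = 2.92e-04, and adjusted p = 0.0196 with an estimated correlation). The inhibitory receptor Btla changed by -0.63 ± 0.12. Marginal zone genes fell in 5 of 13 cases (6 down when adjusted over the list alone; camera adjusted p = 4.00e-04, and adjusted p = 0.19 with an estimated correlation). Cd1d1 changed by -1.08 ± 0.18 and Notch2 by -0.74 ± 0.15. Interferon-stimulated genes fell in 9 of 26 cases (17 down when adjusted over the list alone; camera adjusted p = 1.10e-09, and adjusted p = 0.119 with an estimated correlation). Ifit3 changed by -1.73 ± 0.34. Nedd4 and Klf11 changed by -2.45 ± 0.42 and -2.64 ± 0.58, and Bcl2 changed by -0.21 ± 0.23 (adjusted p = 0.708). Epithelial markers rose in 7 of 13 cases (10 up when adjusted over the list alone; camera adjusted p = 6.20e-10, and adjusted p = 0.102 with an estimated correlation). Fabp2 stood at 32.5 ± 26 and 0.0386 ± 0.0669 CPM, and the retinol carrier Rbp2, without a count in spleen, was at least 116-fold higher over a floor of 3 counts in the group. In all, 838 genes were called, 549 higher and 289 lower. The count was 518, 476 and 545 without the spleen libraries 922, 926 and 950, and 521 and 473 without the PP libraries 926 and 950.

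Between mLN and spleen, BCL2 HEL pos cells differed in 1142 genes, 659 higher and 483 lower (edgeR, adjusted p under 0.05). Axl rose by 4.85 ± 0.31, to 119 ± 39 from 4.08 ± 0.835 CPM, Ccl4 and Ccl3 by 4.19 ± 0.52 and 3.46 ± 0.78, Ccr1 by 3.06 ± 0.33, Nrgn by 3.94 ± 0.44 and Cd63 by 3.27 ± 0.54. Egr2, Nr4a1 and Egr1 were higher by 3.63 ± 0.33, 2.23 ± 0.30 and 2.04 ± 0.25, Cd83 by 1.63 ± 0.16, Bhlhe40 by 2.47 ± 0.22, Lck by 2.29 ± 0.21, Irf4 by 1.11 ± 0.16 and Bcl2a1b by 2.33 ± 0.25. Of 11 follicular genes 4 fell (5 down when adjusted over the list alone; camera adjusted p = 4.69e-06, and adjusted p = 0.0059 with an estimated correlation). Cxcr5 changed by -0.99 ± 0.15, Itgb7 by -1.15 ± 0.15 and Klf2 by -1.59 ± 0.28. Of 13 marginal zone genes 5 fell (5 down when adjusted over the list alone; camera adjusted p = 1.39e-04, and adjusted p = 0.207 with an estimated correlation). Cr2 fell from 587 ± 40.8 to 295 ± 36.3 CPM, and Cd1d1 changed by -0.91 ± 0.18 and Asb2 by -3.95 ± 0.72. Oxidative phosphorylation genes rose in 8 of 26 cases (18 up when adjusted over the list alone; camera adjusted p = 4.46e-08, and adjusted p = 0.207 with an estimated correlation). Secretion genes rose in 9 of 22 (13 up when adjusted over the list alone; camera adjusted p = 5.61e-06, and adjusted p = 0.207 with an estimated correlation). The plasma cell gene Derl3 stood at 2.72 ± 0.29. Erythroid and platelet markers fell in 2 of 5 cases (4 down when adjusted over the list alone; camera adjusted p = 0.0147, and adjusted p = 0.207 with an estimated correlation). Interferon-stimulated genes fell in 7 of 26 cases (15 down when adjusted over the list alone; camera adjusted p = 1.76e-07, and adjusted p = 0.207 with an estimated correlation). Syk changed by -0.88 ± 0.16, the signalling adaptor Malt1 by -0.87 ± 0.12, Myadm by -2.67 ± 0.25 and Nedd4 by -3.17 ± 0.46, while Bcl2 changed by -0.11 ± 0.23 (adjusted p = 0.844). The immediate early list had a median of -0.30 but a camera direction of up (camera adjusted p = 0.0147, and adjusted p = 0.399 with an estimated correlation). The count of 1142 was 679 and 741 without the spleen libraries 926 and 950, 561 without the mLN library 926 and 1946 in a fit of the 6 compared libraries alone.

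PP and mLN differed least in BCL2 HEL pos cells, in 132 genes, 92 higher and 40 lower in PP (edgeR, adjusted p under 0.05). Rab20, a trafficking GTPase, was higher in PP by 2.02 ± 0.29, the kinase Camkk1 by 2.00 ± 0.31, Skil by 1.35 ± 0.19 and the BAFF receptor Tnfrsf13c by 0.84 ± 0.12, and Slamf7 and Bcl2l11 were lower, changing by -1.16 ± 0.18 and -1.35 ± 0.21. Skil and Tnfrsf13c were the 2 called genes of 16 in the TGF-beta response and IgA switching list (5 up when adjusted over the list alone; camera adjusted p = 2.22e-07, and adjusted p = 0.016 with an estimated correlation). Cytosolic ribosomal protein genes fell in 2 of 32 cases (5 down when adjusted over the list alone; camera adjusted p = 3.04e-19, and adjusted p = 0.204 with an estimated correlation). Their median difference from the mLN mean, looked at after the data were seen, was -1.06 in the PP library 950 and -0.28 and -0.36 in 922 and 926. That library also held 0.809% Rn45s, a ribosomal RNA precursor, against 1.79% to 3.97% in the others. Epithelial markers rose in 5 of 13 cases (10 up when adjusted over the list alone; camera adjusted p = 1.31e-18, and adjusted p = 0.0288 with an estimated correlation). Rbp2 was at least 119-fold and Krt8 at least 46.1-fold higher over a floor of 3 counts in the mLN group, in which neither had a count. Fabp1 and Fabp2 stood at 13.6 ± 13.8 and 32.5 ± 26 CPM in PP. Nr4a1 was higher in PP by 1.33 ± 0.28 (adjusted p = 0.0178), a call lost without the mLN library 926, the mLN library 950 or the PP library 950. Bcl2 changed by -0.10 ± 0.23 (adjusted p = 0.945). The count of 132 fell to 69, 25 and 49 without the mLN libraries 922, 926 and 950 and to 58 without the PP library 926 or the PP library 950, and DESeq2 called 249 and a fit without the low-count filter 395.

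Log2 fold changes between tissues were set side by side for HEL pos and BCL2 HEL pos cells, which share no library. Across 11419 genes, which are not independent replicates, Pearson correlations were 0.62 for PP against spleen, 0.63 for mLN against spleen and 0.57 for PP against mLN, and Spearman correlations 0.43, 0.63 and 0.32. Among genes higher in PP than in spleen, 358 were called in both kinds of cells, where independent lists would share 43.6, and among genes lower 185 were called in both against 21.5. For mLN against spleen, 553 were higher in both against 85.2 and 410 lower in both against 55.8, and no gene was called in opposite directions by edgeR in any of the 3 contrasts. Over genes called in HEL pos cells, the slope of the BCL2 HEL pos fold change on the HEL pos fold change was 0.590, 0.540 and 0.571 for PP against spleen, mLN against spleen and PP against mLN. Choosing genes by their HEL pos call lowers this slope even where the effects are equal, and called markers of other cell types enter it. It therefore does not show that tissue effects were smaller in BCL2 HEL pos cells.

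Whether the tissue difference itself differed between BCL2 HEL pos and HEL pos cells was tested with interaction terms. For PP against spleen, edgeR called 1 gene, the Notch target Hes1, with a difference of 1.54 ± 0.22 on the log2 scale (adjusted p = 0.0088), against 1083 genes at an unadjusted p under 0.05 and 60 called by DESeq2. Hes1 stood at 108 ± 7.94 CPM in spleen and 44.9 ± 6.51 CPM in PP HEL pos cells, and at 53.6 ± 6.83 and 67.1 ± 6.87 CPM in BCL2 HEL pos cells. The next genes by p did not pass, Tagap at -1.64 ± 0.30, Bhlhe40 at 1.56 ± 0.29 and Ms4a1, which encodes CD20, at 0.92 ± 0.18, each with adjusted p = 0.0797, and Ccnd2 at 1.39 ± 0.28. Camera called 5 of 31 gene lists for this interaction, and 0 held with the estimated correlation. Among them the marginal zone list had a median of 0.69, with 0 of 13 genes called over all genes. Its camera adjusted p was 5.41e-07, and 0.162 with an estimated correlation. For PP against mLN, edgeR called 1 gene, Cd63, at 3.12 ± 0.50 (adjusted p = 0.0391), against 1132 genes at an unadjusted p under 0.05 and 28 called by DESeq2. The Cd63 call was lost without mLN HEL pos Pool, 392 or 399, PP HEL pos 399, mLN BCL2 HEL pos 922, 926 or 950, or PP BCL2 HEL pos 926 or 950. Ccl4, Nfat5 and Mthfd2 differed by 2.66 ± 0.54, -1.86 ± 0.36 and 1.47 ± 0.30 without passing (adjusted p = 0.14 each). The first count was 23 without PP HEL pos 392, 6 without spleen HEL pos 392, and 2 without PP HEL pos Pool, spleen HEL pos 399, spleen BCL2 HEL pos 922 or 950, or PP BCL2 HEL pos 922 or 926, and 3 without the pooled HEL pos libraries. The second was 8 without PP HEL pos 392 and 2 without PP BCL2 HEL pos 922 or mLN BCL2 HEL pos 926. It was 0 without mLN HEL pos Pool, 392 or 399, PP HEL pos 399, mLN BCL2 HEL pos 922 or 950, PP BCL2 HEL pos 926 or 950, or the pooled HEL pos libraries.

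**Figure D3:**
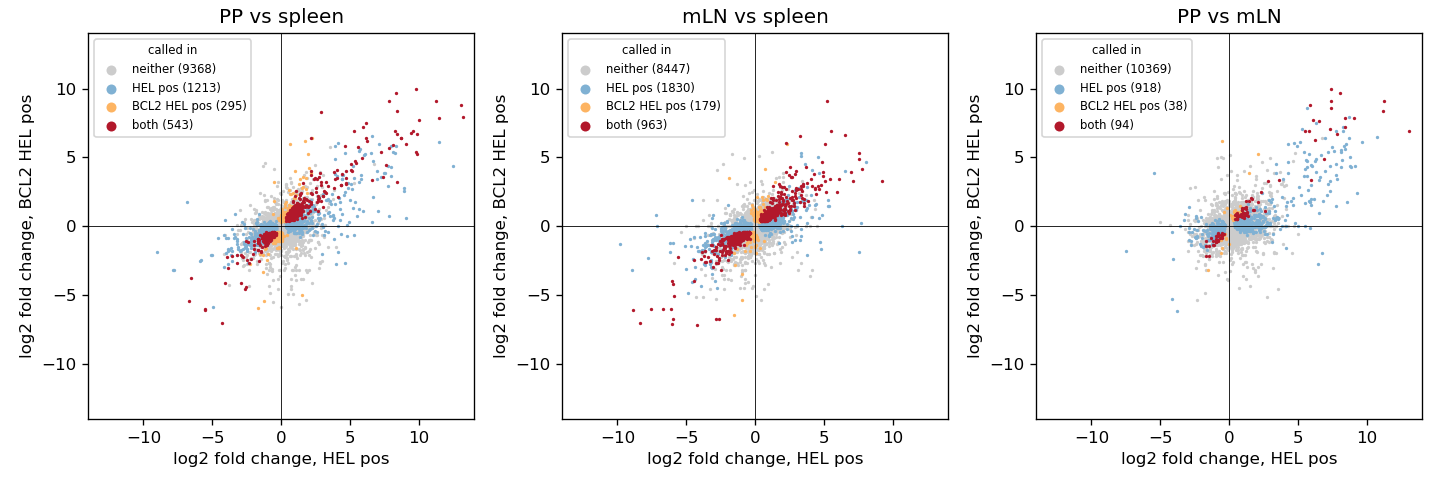
Log2 fold change between tissues in HEL pos cells (horizontal) and in BCL2 HEL pos cells (vertical) for each of 11419 genes, in panels for PP against spleen, mLN against spleen and PP against mLN, coloured by the kind of cell in which edgeR called the gene. Every gene called in both lies in a quadrant where the signs are equal, 358 higher and 185 lower for PP against spleen.

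BCL2 HEL pos cells were compared with HEL pos cells within each tissue. Bcl2 was higher in BCL2 HEL pos cells by 1.28 ± 0.24 in spleen, 1.11 ± 0.23 in mLN and 1.19 ± 0.24 in PP on the log2 scale, and spleen held 168 ± 20.7 against 69.7 ± 18.7 CPM (SD, n = 3). Against the pooled HEL pos library alone, with the spread taken from the other groups, Bcl2 stood at 0.65 in mLN and 0.71 in PP and its calls there were lost (adjusted p = 0.147 and 0.0853). Bcl2 lies on chromosome 1 from 106538178 to 106714274 (mm10). A pseudogene of a ribosomal protein, Rps15a-ps6 (chromosome 11 from 6172644 to 6173036), was higher by 5.03 ± 0.34, 4.90 ± 0.32 and 4.30 ± 0.33, and its reads can be shared with its parent gene. The heat shock genes Hspa1a and Hspa1b, a near-identical pair whose split is uncertain, were higher by 4.79 ± 0.56 and 5.04 ± 0.73 in spleen and by 4.20 ± 0.56 and 3.33 ± 0.70 in mLN. Lef1, a transcription factor of immature B cells, was lower, changing by -2.40 ± 0.42 in spleen, -2.56 ± 0.38 in mLN and -3.89 ± 0.44 in PP, and Egr1 by -1.15 ± 0.25, -1.63 ± 0.23 and -1.23 ± 0.22. Against the pooled library alone the Egr1 call in spleen was lost, at -0.72 (adjusted p = 0.29).

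In spleen, 1070 genes were called between BCL2 HEL pos and HEL pos cells, 520 higher and 550 lower (edgeR, adjusted p under 0.05). Transitional and immature B cell genes fell in 6 of 8 cases (6 down when adjusted over the list alone; camera adjusted p = 5.78e-08, and adjusted p = 0.0149 with an estimated correlation). Cd93 changed by -3.15 ± 0.44. Follicular genes rose in 3 of 11 cases (5 up when adjusted over the list alone; camera adjusted p = 6.08e-04, and adjusted p = 0.0254 with an estimated correlation). Itgb7 stood at 0.68 ± 0.15. Marginal zone genes had 7 down and 1 up of 13, and 10 down and 1 up when adjusted over the list alone. Camera gave that list an adjusted p of 1.355e-04, and 0.311 with an estimated correlation. Interferon-stimulated genes had 10 up and 1 down of 26 (10 up and 1 down when adjusted over the list alone; camera adjusted p = 4.44e-05, and adjusted p = 0.311 with an estimated correlation), Oasl2 at 1.47 ± 0.20. Genes of antigen presentation rose in 6 of 14 cases (8 up and 2 down when adjusted over the list alone; camera adjusted p = 0.00128, and adjusted p = 0.311 with an estimated correlation). The class II chain H2-Aa stood at 0.58 ± 0.14 and Icosl at 1.07 ± 0.15. The immediate early genes Ier2 and Klf6 rose by 1.17 ± 0.24 and 0.85 ± 0.14. Uhrf1 changed by -2.57 ± 0.24, Ldha by -0.68 ± 0.14, Bhlhe40 by -1.57 ± 0.22, the Fc receptor-like gene Fcrl5 by -1.53 ± 0.33, Ccr1 by -2.29 ± 0.33, the proapoptotic Bid by -0.93 ± 0.17 and Bcl2a1b by -1.39 ± 0.25. Granulocyte markers fell in 4 of 6 cases (camera adjusted p = 1.37e-07, and adjusted p = 0.0362 with an estimated correlation), with S100a8 at 0.116 ± 0.201 and 49.2 ± 47.5 CPM and Camp at 0 ± 0 and 7.68 ± 6.82 CPM. The count was 713 and 645 without the HEL pos libraries 392 and 399, 683, 569 and 638 without the BCL2 HEL pos libraries 922, 926 and 950, and 306 with the pooled library as the whole HEL pos group.

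In mLN, 1334 genes were called, 660 higher and 674 lower in BCL2 HEL pos cells (edgeR, adjusted p under 0.05). Anergy and tolerance genes fell in 8 of 24 cases (2 up and 9 down when adjusted over the list alone; camera adjusted p = 7.36e-04, and adjusted p = 0.0226 with an estimated correlation). Cd5 changed by -3.13 ± 0.40, Folr4 by -3.05 ± 0.53 and Egr2 by -1.57 ± 0.27. Follicular genes rose in 6 of 11 cases (8 up when adjusted over the list alone; camera adjusted p = 1.75e-07, and adjusted p = 0.00161 with an estimated correlation). S1pr1 changed by 1.16 ± 0.14 and Itgb7 by 1.24 ± 0.15. Antigen presentation genes rose in 5 of 14 (8 up when adjusted over the list alone; camera adjusted p = 6.67e-06, and adjusted p = 0.168 with an estimated correlation). Icosl changed by 1.51 ± 0.16. The inhibitory receptors Fcgr2b and Cd22 rose by 1.07 ± 0.12 and 0.83 ± 0.12, Notch2 by 1.03 ± 0.15 and Jun by 1.67 ± 0.22. By contrast Cd63 changed by -3.88 ± 0.37, Jup by -3.44 ± 0.45, osteopontin (Spp1) by -5.06 ± 0.76, the adhesion receptor Gpr56 by -4.28 ± 0.63 and Nedd4 by -3.93 ± 0.45. DNA replication genes fell in 8 of 23 cases (9 down when adjusted over the list alone; camera adjusted p = 1.70e-06, and adjusted p = 0.118 with an estimated correlation). Uhrf1 changed by -1.90 ± 0.22. Secretion genes fell in 9 of 22 (9 down when adjusted over the list alone; camera adjusted p = 4.54e-05, and adjusted p = 0.249 with an estimated correlation). Pdia6 changed by -0.96 ± 0.19. The transitional list had 3 of 8 genes down (4 down when adjusted over the list alone; camera adjusted p = 0.00176, and adjusted p = 0.11 with an estimated correlation). The progenitor regulator Myb stood at -4.23 ± 0.80. Myc changed by -1.29 ± 0.18, Ldha by -0.83 ± 0.14 and the survival gene Bcl2l1 by -1.77 ± 0.25, and Mapk12, carbonic anhydrase (Car2), Smagp and the sterol hydroxylase Cyp27a1 rose by 3.53 ± 0.62, 3.22 ± 0.46, 3.06 ± 0.49 and 2.81 ± 0.25. T and NK cell markers fell in 7 of 14 cases (7 down when adjusted over the list alone; camera adjusted p = 5.95e-05, and adjusted p = 0.193 with an estimated correlation), Cd3d from 7.83 ± 5.11 to 0.941 ± 0.28 CPM. The count of 1334 was 654 and 716 without the HEL pos libraries 392 and 399, 773, 866 and 727 without the BCL2 HEL pos libraries 922, 926 and 950, 206 against the pooled library alone and 2105 in a fit of the 6 compared libraries.

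In PP, 1150 genes were called, 609 higher and 541 lower in BCL2 HEL pos cells (edgeR, adjusted p under 0.05). Transitional and immature genes fell in 4 of 8 cases (4 down when adjusted over the list alone; camera adjusted p = 1.65e-06, and adjusted p = 0.0205 with an estimated correlation). Cd93 changed by -2.99 ± 0.44 and Myb by -4.37 ± 0.91. Anergy and tolerance genes had 5 down and 1 up of 24 (2 up and 6 down when adjusted over the list alone; camera adjusted p = 0.0323, and adjusted p = 0.143 with an estimated correlation). Cd5 stood at -2.32 ± 0.39 and Folr4 at -2.79 ± 0.57. Interferon-stimulated genes rose in 7 of 26 cases (8 up when adjusted over the list alone; camera adjusted p = 0.00211, and adjusted p = 0.614 with an estimated correlation). Oasl2 changed by 1.54 ± 0.20 and Ly6a by 1.25 ± 0.21. Antigen presentation genes rose in 5 of 14 (10 up when adjusted over the list alone; camera adjusted p = 7.69e-06, and adjusted p = 0.196 with an estimated correlation). Icosl changed by 0.90 ± 0.15. Follicular genes rose in 4 of 11 cases (5 up and 1 down when adjusted over the list alone; camera adjusted p = 0.0255, and adjusted p = 0.143 with an estimated correlation). Itgb7 changed by 1.16 ± 0.15. Fcgr2b rose by 1.04 ± 0.12, Jun by 1.65 ± 0.22, Trim21 by 2.28 ± 0.41, Car2 by 3.00 ± 0.45, Smagp by 3.27 ± 0.51 and Irak3, which restrains Toll-like receptor signalling, by 1.10 ± 0.19. The complement gene Cfp changed by -3.13 ± 0.32, Gpr56 by -3.91 ± 0.61, Nedd4 by -3.19 ± 0.41 and Il5ra by -1.69 ± 0.29. Epithelial markers fell in 5 of 13 cases (8 down when adjusted over the list alone; camera adjusted p = 3.03e-05, and adjusted p = 0.242 with an estimated correlation), Krt8 from 36.4 ± 21.5 to 5.35 ± 3.45 CPM, a call lost by DESeq2 and without the HEL pos libraries 399 and Pool. The count of 1150 was 670 without the HEL pos library 399, 638 without the BCL2 HEL pos library 950, 255 without the HEL pos libraries 399 and Pool, 341 against the pooled library alone and 286 in a fit of the 6 compared libraries.

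In all 3 tissues 267 genes were called in the same direction between BCL2 HEL pos and HEL pos cells, 157 higher and 110 lower, and 1 gene was called in all 3 with mixed direction. Independent lists would share 1.60 and 1.54, but the same library numbers recur in the 3 tissues, so the lists may not be independent. Bcl2, Rps15a-ps6, Icosl, Itgb7 and Jun were among those higher, and Lef1, Egr1, Cd93, Uhrf1 and Gpr56 among those lower. The HEL pos groups held Y-linked transcripts in their pooled library alone, whereas every BCL2 HEL pos library held them.

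**Figure D4:**
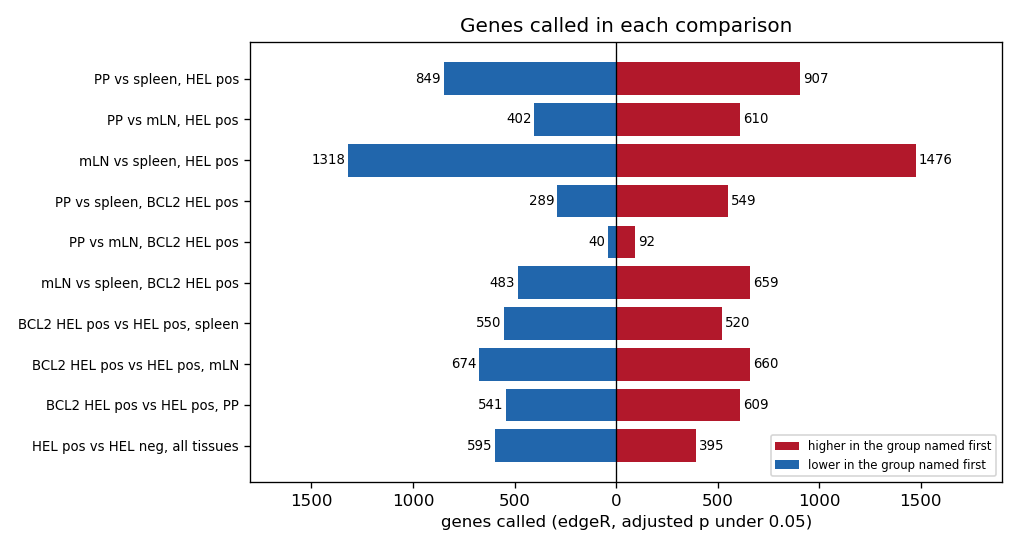
Number of genes called higher (right) and lower (left) in the group named first in each comparison, by edgeR at an adjusted p under 0.05. The bars are longest for mLN against spleen HEL pos cells, 1476 and 1318, and shortest for PP against mLN BCL2 HEL pos cells, 92 and 40.

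HEL pos cells were compared with HEL neg cells over the 3 tissues at once, since each tissue has 1 pooled HEL neg library and so no replicate of these cells. All 3 HEL neg libraries are labelled as a pool and may come from 1 pool of mice, which the fit treats as independent. Germinal centre genes were lower in HEL pos cells: the confinement receptor S1pr2 at -4.54 ± 0.48 on the log2 scale, Mef2b at -3.96 ± 0.33 and the DNA glycosylase Neil1 at -2.39 ± 0.22 (SE, 9 HEL pos and 3 HEL neg libraries). S1pr2 stood at 54, 74.8 and 225 CPM in HEL neg cells of spleen, mLN and PP, and at 6.73 ± 3.93, 3.9 ± 2.29 and 3.58 ± 2.66 CPM in HEL pos cells (adjusted p = 8.34e-05). Proliferation genes were lower as well, Mki67 at -2.95 ± 0.34, Cdk1 at -2.63 ± 0.33 and Top2a at -1.83 ± 0.23.

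Of 20 germinal centre genes 15 fell (18 down when adjusted over the list alone; camera adjusted p = 4.47e-26, and adjusted p = 0.0132 with an estimated correlation). Gcet2, a member of that list under the newer symbol Gcsam, changed by -6.13 ± 0.74. Mitosis genes fell in 21 of 24 cases (23 down when adjusted over the list alone; camera adjusted p = 3.93e-33, and adjusted p = 0.0132 with an estimated correlation). DNA replication genes fell in 13 of 23 (17 down when adjusted over the list alone; camera adjusted p = 2.55e-13, and adjusted p = 0.131 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 stood at -2.26 ± 0.26. The memory gene Anxa2 was lower, changing by -4.43 ± 0.36, Igj by -4.07 ± 0.49 and Cd7 by -4.80 ± 0.58. Hivep3 was higher by 2.31 ± 0.31, and Tnfsf4, which encodes OX40 ligand and had no count in HEL neg cells, stood at 28.3 ± 1.33 CPM in mLN, 4.84 ± 3.3 CPM in PP and 0.114 ± 0.197 CPM in spleen HEL pos cells. Gpr56 was higher by 4.14 ± 0.58, Ifitm2 by 4.04 ± 0.64 and the proapoptotic Bmf by 1.70 ± 0.28, and Icosl was lower, changing by -1.58 ± 0.22. Transitional genes rose in 4 of 7 cases (4 up when adjusted over the list alone; camera adjusted p = 7.54e-04, and adjusted p = 0.136 with an estimated correlation). Cd93 changed by 2.12 ± 0.40 and Lef1 by 1.99 ± 0.45. Interferon-stimulated genes had 7 up and 1 down of 26 (7 up and 1 down when adjusted over the list alone; camera adjusted p = 5.44e-04, and adjusted p = 0.427 with an estimated correlation), Mx1 at 2.26 ± 0.39. The calls of Cd93 and Lef1 were lost without the PP HEL neg library, those of Lef1 and Spp1 (5.55 ± 1.00) without the mLN HEL neg library, and that of Nr4a3 (3.09 ± 0.73) without either. Between the pooled libraries Nr4a3 differed at -0.09 in spleen, 3.03 in mLN and 2.49 in PP, and Lef1 at 0.23, 3.88 and 2.13, so the spleen showed little of either difference. Bcl2 changed by -0.48 ± 0.21 (adjusted p = 0.174), but was called at -0.78 without the pooled HEL pos libraries and at -0.49 without the low-count filter (adjusted p = 0.00597 and 0.0335). In all, 990 of 11406 genes were called, 395 higher and 595 lower (edgeR, adjusted p under 0.05). The count was 1574, 189 and 176 without the spleen, mLN and PP HEL neg libraries, 602 and 644 without the mLN HEL pos libraries 392 and 399, 1551 by DESeq2, 1495 without the low-count filter and 2039 in a fit of all 21 libraries, with 1047 higher and 992 lower. A fit of the 6 pooled libraries alone, 1 of each kind per tissue, called 73 genes, 11 higher and 62 lower, and in it the calls of Gpr56, Ifitm2, Cd93, Lef1, Mx1, Icosl and Bmf were lost.

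**Figure D5:**
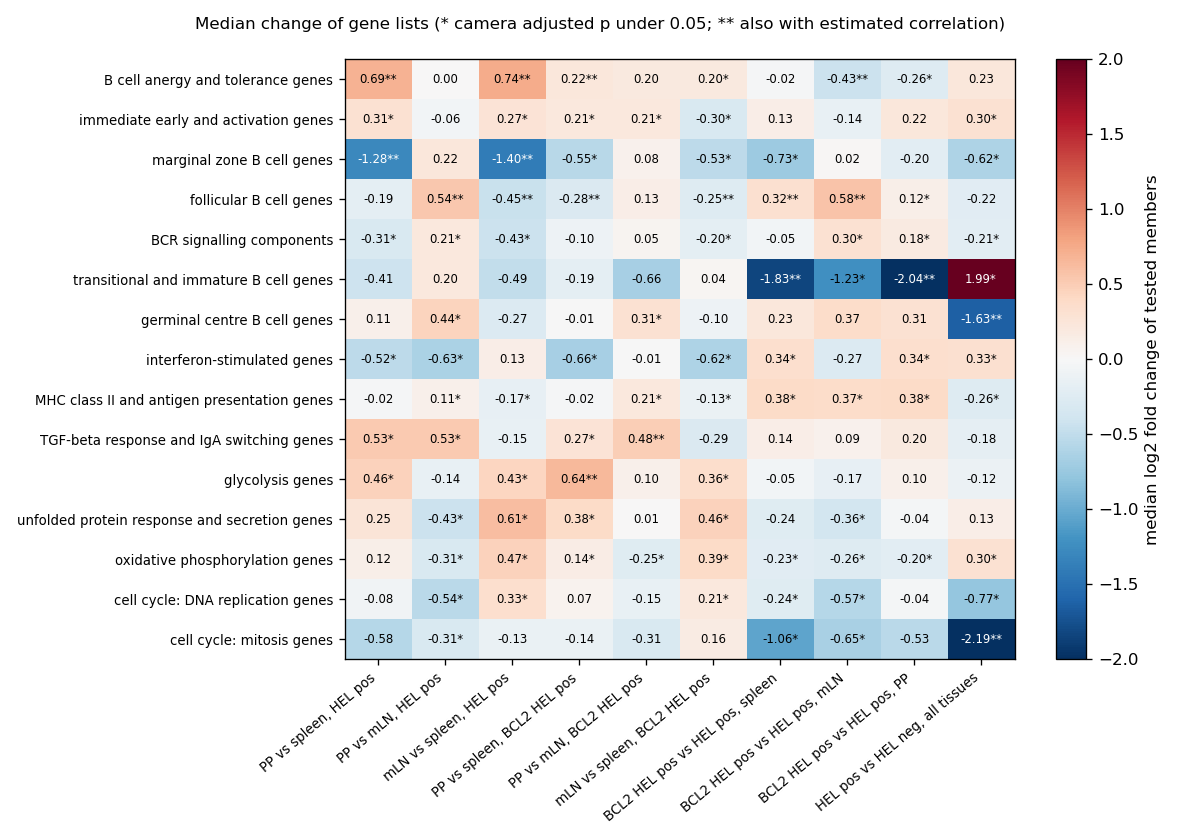
Median log2 fold change over the tested members of gene lists (vertical) in each comparison (horizontal), positive where the group named first was higher, with 1 star for a camera adjusted p under 0.05 and a pair of stars where the call also held with an estimated correlation. The median of the mitosis list is -2.19 and that of the germinal centre list -1.63 between HEL pos and HEL neg cells.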

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

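The splits reported here were planned before the results were seen, and the fit without the pooled libraries and the sorting of splits by tissue were chosen after. Hes1 stood out because its difference between PP and spleen was not the same in BCL2 HEL pos and HEL pos cells, by 1.54 on the log2 scale, and edgeR called it under every alternative tried. Cd63 stood out because its difference between PP and mLN was not the same in the 2 kinds of cells, by 3.12, and that call was lost without any 1 of 9 libraries and without the pooled HEL pos libraries (adjusted p = 0.065). For the count of 1 gene in either interaction the splits of the libraries leave chance undecided: 13 of 100 gave at least 1 gene for PP against spleen, the highest other 1088, and 8 of 100 for PP against mLN, the highest other 252. The splits that gave 1088 and 252 kept the tissues apart in HEL pos cells and mixed them in BCL2 HEL pos cells, so they carry the difference between tissues. With tissues mixed in both kinds of cells, 3 and 2 of 85 splits gave at least 1 gene, the highest 19 and 2.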

How the results depend on the processing

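The alternatives without the pooled libraries, against the pooled library alone and without PP HEL pos 399 and Pool were chosen after the results were seen, the others before. Of 165 alternative counts of called genes, 83 lay within 1.5 times the main count, and the cause of the other shifts was not tested beyond the smaller number of libraries in some fits. Fits of the compared libraries alone called 800 (PP against spleen) and 344 (PP against mLN) genes in HEL pos cells, 1946 for mLN against spleen in BCL2 HEL pos cells, and 2105 and 286 for BCL2 HEL pos against HEL pos cells in mLN and PP. Without PP HEL pos 399 and Pool the counts were 640, 209 and 255 for PP against spleen, PP against mLN and BCL2 HEL pos against HEL pos in PP. Against the pooled library alone BCL2 HEL pos cells gave 306, 206 and 341 genes in spleen, mLN and PP. Without the pooled libraries PP against mLN gave 551 and the interactions 3 and 0. DESeq2 and no filter gave 249 and 395 for PP against mLN in BCL2 HEL pos cells, 60 and 114 and then 28 and 111 for the interactions, and 1551 and 1495 for HEL pos against HEL neg cells, which gave 2039 with all 21 libraries. Leaving out 1 library gave 1307 to 2135 (PP against spleen), 374 to 1512 (PP against mLN) and 2023 to 2528 (mLN against spleen) in HEL pos cells, 473 to 866, 25 to 98 and 561 to 862 in BCL2 HEL pos cells. It gave 569 to 911, 654 to 1192 and 638 to 1638 for BCL2 HEL pos against HEL pos cells in spleen, mLN and PP, and 1 to 23 and 0 to 8 for the interactions and 176 to 1574 for HEL pos against HEL neg cells. Where higher and lower counts were close, as for PP and mLN against spleen in HEL pos cells and for BCL2 HEL pos against HEL pos cells, some alternatives turned which was larger. With the replicate block PP against mLN gave 1634 in HEL pos cells (843 higher, 791 lower), the BCL2 HEL pos comparisons 1388 (PP against spleen), 480 (PP against mLN, 237 higher and 243 lower) and 1773 (mLN against spleen), the interactions 48 and 13, and the 6 pooled libraries of HEL pos and HEL neg cells 73 (11 higher, 62 lower). The labels give the libraries a shared number without saying what it marks. Same-number correlations of deviations were 0.02 to 0.31 in HEL pos and 0.05 to 0.20 in BCL2 HEL pos cells, with 7 of 9 and 6 of 9 pairs over 0.1 and other pairs at most 0.10 and 0.05. In HEL pos cells 6 of 9 libraries and in BCL2 HEL pos cells 9 of 9 correlated best with their own number, a hint from the data, not the design. Of 143 camera calls 23 held with an estimated correlation. The 10 splits of 6 libraries are too few for a share under 0.05. The real split was the 1 with the most genes, and the highest other gave 22 for PP against spleen in HEL pos cells and 0 by edgeR for the other 8 comparisons. For HEL pos against HEL neg cells 1 of 64 splits gave 990 genes, the highest other 60. Those splits treat the tissues as independent, but the same pool and numbers recur across tissues and HEL neg cells come only as pools. They therefore do not exclude chance. Leaving out immunoglobulin genes and the shares of immunoglobulin classes were not run, since the table names none. Depth limits genes near the floor of 3 counts.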

Other observations

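The tests below were chosen after the results were seen, except that of epithelial RNA, which was planned. Pooled libraries of HEL pos and HEL neg cells were set side by side within each tissue, 1 library each and so with no replicate check. The median log2 difference of the germinal centre list was -0.86 in spleen, -1.84 in mLN and -2.39 in PP, below all 10000 random lists of like size and expression in each tissue. The transitional and immature list stood at 1.09, 1.30 and 1.64, but its members split. Cd93, Sox4, Myb and Lef1 were higher in each tissue. Cd24a was lower in mLN and PP, at -1.25 and -0.55, and so was Vpreb3, at -0.89 and -0.53. In spleen these stood at 0.42 and 1.09, and Tmsb10 was slightly lower in each tissue. The anergy and tolerance list stood at -0.21 in spleen (percentile 0.74), 0.46 in mLN (percentile 99.9) and 0.18 in PP (percentile 93.1). T and NK cell markers stood at -2.34, 1.48 and -1.71, and the anergy list holds Cd5 and Folr4, also known from T cells. Between mLN and spleen HEL neg cells Nr4a1, Egr1, Egr2 and Egr3 differed at -0.18, 0.83, 0.81 and 0.73, against 2.85, 2.62, 4.65 and 2.20 in the pooled HEL pos libraries. Between PP and spleen they differed at 0.67, 0.44, 1.10 and 0.69, against 2.96, 2.85, 4.25 and 2.91.

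Nr4a1, Egr1, Egr2 and Egr3 were higher in mLN and PP than in spleen HEL pos cells, with a median of 2.71 for mLN against spleen. Handling of the tissue before sorting would raise other immediate early genes alike. For mLN against spleen, 10 others had a median of -0.70 (SD 0.83), with 0 called higher and 4 lower. These 10 leave out Nr4a2, Nr4a3, Myc, Cd69, Cd83 and Cd86 of the same list, a choice made after the data were seen. Over all 20 tested members, 8 rose and 4 fell, with a median of 0.27. The values thus speak against handling for the 10 genes only. T cells among the sorted cells stay open as a source: Cd3d, Cd3e and Cd3g had a median of 1.97 for mLN against spleen in HEL pos cells, where 2 of the 3 rose. Their median was 0.39 for PP against spleen in HEL pos cells, and in BCL2 HEL pos cells -1.50 for mLN and -1.59 for PP against spleen, where the 4 genes had medians of 2.13 and 3.01, but no Cd3 gene was called and levels lay near the floor of 3 counts. Differences between the organs, antigen receptor signalling included, were not tested and stay open.

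Between BCL2 HEL pos and HEL pos cells 267 genes were called in the same direction in all 3 tissues. Sex is a candidate source, since Y-linked transcripts are nearly missing from the HEL pos libraries 392 and 399, but of 295 genes called without the pooled libraries, at least 67.0% of the median difference was left against the pooled library, which holds those transcripts. A single chromosome segment of another strain would gather the genes, but the fullest of the fixed-length windows held 5.76% of the 243 genes with coordinates. That window, on chromosome 17 with Hspa1a, Hspa1b and H2 genes, held 14 genes against a median of 10 in random sets, of which 35 of 1000 were as full, so linkage stays open for its genes. Batch and the origin of the BCL2 HEL pos cells were not separable from the groups and stay open.

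Enterocyte transcripts were found in all 7 PP libraries. RNA of gut epithelial cells carried into the PP suspension may be their source, but this stays open because 53.8% of 13 tested epithelial genes were higher in every PP library than in every other, between the bounds set in advance. Of the genes that were not, Krt18 and Krt19 had a lowest PP value of 0 CPM. Vil1, Reg3b and Cldn7 had a lowest PP value of 0.128 CPM, below the floor of 3 counts. Epcam reached 35.3 CPM outside PP. For these genes the test could not decide, and their values do not speak against such RNA. A general background in the PP libraries would raise receptor genes of the nose too, but in BCL2 HEL pos cells their PP to spleen ratio was 0.777, where that of enterocyte transcripts was at least 747 over a floor of 3 counts in spleen. In HEL pos cells the ratio was 2.13 and at most 9.19 between any PP and spleen library, where that of enterocyte transcripts was at least 150. Neither HEL neg cells, with 1 library each and a receptor ratio of 2.37, nor a biological explanation was tested.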
